A study of Mus musculus with 2 samples.

How the data were processed

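Outflow tract regions of the embryonic heart were collected at embryonic day 9.5 from ICR mouse embryos of a control group and of a group treated with retinoic acid (RA), the active derivative of vitamin A. The series design gives approximately 200 regions, without saying whether per group or in all. Per the labels' protocols, the regions were kept in an RNA stabilization reagent, total RNA was purified on columns, and biotinylated cRNA was made from 6 ug of total RNA by the standard Affymetrix procedure. The dose, route and time of RA treatment are not given in the sources used here. There was 1 array per group, each from a pool of tissue, so the 2 arrays hold no replicate and no value has a spread between pools.

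The deposited values are linear MAS5 signal intensities, 1 per probe set and array, and per the submitters' processing notes the authors made them with MAS5. The version, detection calls and masks are not given in the sources used here. The scaling was read from the deposited intensities themselves: after 2% was trimmed from each end, the mean was 500.06 on the control array and 500.003 on the RA-treated array, so each array had been scaled to a common target. This scaling sets the average change to near 0, and a gene at a ratio of 1 is unchanged only relative to the other transcripts. Signals ran from 0.1 to 37266 on the control array and from 0.1 to 53157 on the RA-treated array. No column of per-sample values was left unmapped.

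Of 45101 probe sets, 64 were control probe sets and 45037 were not. Probe sets were named through the platform annotation, with symbols checked by gene identifier against the RefSeq table of assembly GRCm38.p6. 34945 probe sets named exactly 1 gene, 932 named several and were not used, and 9160 have no gene name here. No coordinates are given, because the build behind the array's annotation is not stated. Some genes of the fixed lists are not reported here. Each gene was given the value of its probe set with the highest mean log2 signal, with probe sets ending in _x_at taken only where the gene had no other, which left 18193 genes.

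A floor was set at the 40th percentile of each array (47.1 on the control array and 58.1 on the RA-treated array), and lower signals were raised to it. Because no detection calls were used, the floor is a working limit and not a detection limit. The log2 ratio of RA-treated over control was then taken. A gene above the floor on only 1 array gives a lower bound of its fold ("at least"), provided that its signal also exceeds the floor of the other array. The floor of the RA-treated array is the higher one, so 366 genes above the floor on the control array only, with a control signal not above 58.1, have ratios of 0 or more although their RA-treated signal is under the floor; these ratios are no bound and show no direction. They stay in the list medians as the fixed rule has it, and medians without them were added as an alternative. The number of arrays limits the precision: no significance test was made and no p-value is given. The files turned out to hold the unit that had been assumed.

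The error of a ratio that comes from the array alone was estimated from 5072 genes with a second probe set above the floor on both arrays, as the SD of the difference of the 2 log2 ratios divided by the square root of 2. This probe-set SD was 0.53 below a mean signal of 364, 0.48 between 364 and 937, 0.40 above 937 and 0.48 for all. It includes true differences between transcript forms and leaves out the spread between pools of embryos.

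For 30 gene lists, the median log2 ratio of the members above the floor on at least 1 array was set against 10000 random lists of the same size matched on mean signal (20 bins). A list whose percentile lay above 97.5 or under 2.5 was called apart from random lists, as a description of these 2 arrays; lists with fewer than 5 such members have no percentile. Of the 27 lists with a percentile, chance would place 1.35 outside these limits if list members varied independently. The lists, the floor, the 2-fold threshold and the alternatives were fixed before the data were examined, as was the rule for named genes. The rule takes the 15 highest and 15 lowest ratios among genes above the floor on both arrays with a mean signal over 390 (the 60th percentile of genes), the 5 brightest genes per direction above the floor on 1 array only, from each list the 4 largest ratios and any member at 2-fold or more, and Tbx2, Tgfb2, Cyp26a1 and Rarb. Transcripts without a proper name were left out of the first parts. Members of the lists named outside this rule (Bmp4, Cyp26b1, Fgf8, Fgf10, Gata4, Gli1, Hand2, Has2, Nkx2-5, Nppa, Nr2f1, Nr2f2, Ptprc, Smyd1, Tbx5, Tek, Tyrobp, Vcan and Wnt11) were chosen after their values were seen. Tbx2 and Tgfb2 were chosen because published work on such embryos concerns them, so their values are not independent evidence.

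The alternatives were median, loess and quantile scaling, floors at the 20th and 60th percentiles, a pseudocount in place of the floor, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at or _s_at, and thresholds of 1.5-fold and 3-fold. Scaling to the spiked-in hybridization controls, leaving out the genes between the floors, and lists of only the members above the floor on both arrays were added after seeing the data. The procedure was tested on simulated data in which 200 genes were changed and each ratio had an SD of 0.48. A log2 change of 2 was called in 100% of the genes raised and 94% of those lowered, and a log2 change of 1 in 54% and 52%. The changed genes all had signals above 200 on both arrays, and the same SD was used at every level. These rates therefore do not hold for dimmer genes. Of 11759 unchanged genes, 379 passed the 2-fold threshold by this noise alone (3.22%). Of 200 simulated unchanged lists of 15 genes 2.5% were called apart, and of 200 lists shifted by 0.5 on the log2 scale 90.5% were called higher. The simulated noise was independent between probe sets, so these rates do not hold for lists whose members vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 (loess) and matplotlib 3.10.9 were used.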

Results

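Gene expression in the outflow tract region of the embryonic day 9.5 mouse heart was measured on 1 Affymetrix array from control embryos and 1 from RA-treated embryos, to find genes that take part in the altered outflow tract development of RA-induced heart defects. The comparison is therefore between 2 pools of tissue, without replicates. 11508 of 18193 genes had a signal above the floor on both arrays, and their log2 signals correlated across genes with r = 0.96 (genes are not independent replicates). This does not measure how well a ratio is reproduced. Log2 ratios of 2 probe sets of the same gene correlated with r = 0.44 over 5072 genes. Median signals over probe sets were 77.8 on the control array and 96.0 on the RA-treated array. The spiked-in hybridization controls, which are added in fixed amounts, were 1.49-fold higher on the RA-treated array (median of 18 probe sets, log2 ratio 0.58). The 24 probe sets of the spiked-in poly-A controls were 2.08-fold lower (median log2 ratio -1.05). The ratio of 3' to 5' signal, a sign of RNA integrity and labelling, was 1.31 in the control and 1.42 in the RA-treated pool for Actb, 0.83 and 0.86 for Gapdh, 3.002 and 5.59 for the transferrin receptor Tfrc, and 2.29 and 3.38 for the dimmer pyruvate carboxylase Pcx.

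Between the pools, the transcription factor gene Tbx2 lay furthest below control among properly named genes above both floors with a mean signal over 390. Genes of the response to low oxygen were among those furthest above. 592 genes (5.14% of those above the floor on both arrays) were at least 2-fold higher in the RA-treated pool and 284 (2.47%) at least 2-fold lower. A further 149 genes were at least 2-fold above the floor on the RA-treated array only, and 37 on the control array only. This imbalance turned round with the scaling: the counts were 81 and 98 after loess, and 77 and 99 after quantile scaling. Quantile scaling gave 497 higher and 394 lower genes, and scaling to the hybridization controls, which moved the median of all genes to -0.59, gave 157 higher and 2279 lower. In simulated unchanged data with the probe-set error of these arrays, 379 of 11759 genes passed the same threshold, so single genes near 2-fold are within the array's own error. Fold values below are relative to the deposited scaling. Other values of genes and probe sets below are log2 ratios, except signals, which are given as control and then RA-treated.

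**Figure D1:**
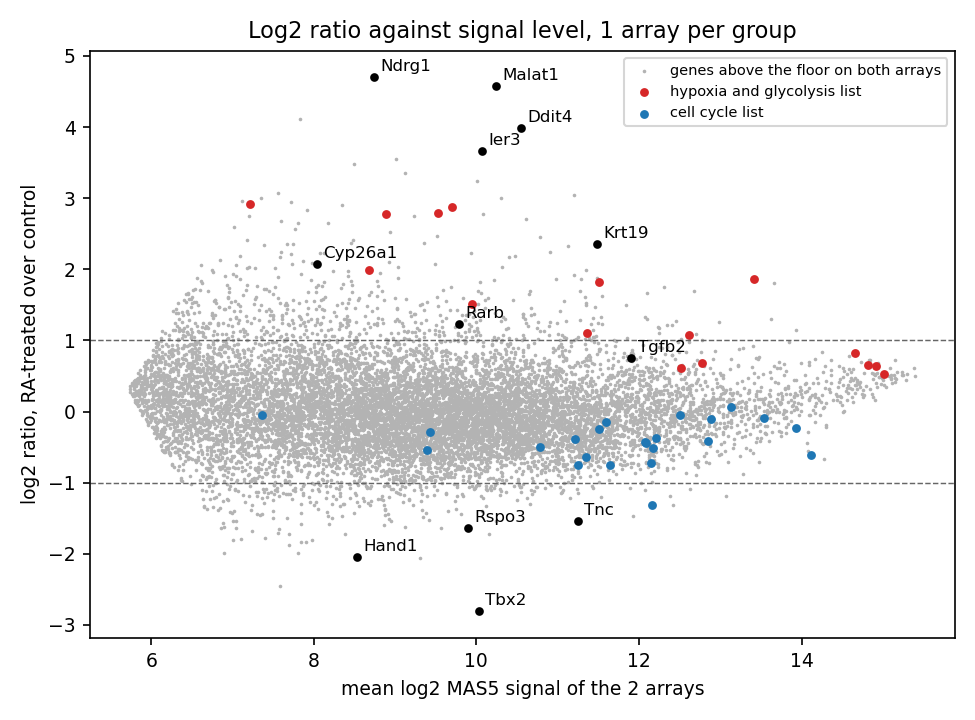
Log2 ratio of RA-treated over control (vertical axis) against the mean log2 MAS5 signal of the 2 arrays (horizontal axis), 1 point per gene above the floor on both arrays, with dashed lines at 2-fold. Members of the hypoxia and glycolysis list (red) all lie above 0 and Tbx2 lies lowest of the labelled genes, at -2.81; the brightest genes lie above 0 as a group.

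Tbx2, a T-box repressor of chamber myocardium genes in the outflow tract and atrioventricular canal, had a signal of 2773 in the control and 396 in the RA-treated pool, 7.0-fold lower (log2 ratio -2.81, probe-set SD 0.40). This value rests on 1 probe set, since no other probe set used here names Tbx2. Tgfb2, a ligand for the transition of endocardium to cushion mesenchyme, was not lower with the deposited scaling. Its brightest probe set read 2960 and 4973, a log2 ratio of 0.75 (probe-set SD 0.40), and its 3 other probe sets ranged from -0.05 to 0.42. Under scaling to the hybridization controls, which lowers every ratio alike, only the brightest probe set would stay above 0. Of the T-box list, Tbx2 was the only one of 6 measured members at least 2-fold lower on its brightest probe set. Tbx20 read -0.60 there, and its 2 other probe sets read -1.34 (2.54-fold lower) and -0.51. Tbx5 had no settled direction (-0.43, and 0.53 on its other probe set), and Tbx18 was 2.11-fold higher (log2 ratio 1.08) on its brightest probe set but read 0.22 on the other. The list's median (0.05, but -0.06 after loess and -0.12 after quantile scaling) and mean (-0.25) differed in sign, and the median lay at a percentile of 58.3 among matched random lists. The bHLH factor gene Hand1, a regulator of the developing heart, was 4.14-fold lower (753 and 182). Its second probe set was lower as well, with -3.18 as a bound because its RA-treated signal was under the floor.

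Cushion mesenchyme and matrix genes were lower as a group. Their median log2 ratio was -0.46 over 22 members, at a percentile of 0.01, and 4 members were at least 2-fold lower while none was 2-fold higher. These were Postn, a matricellular protein of valve mesenchyme (3.66-fold, 397 and 108), the matrix glycoprotein gene Tnc (2.91-fold, 4157 and 1430), the homeobox gene Msx2 (2.71-fold) and Fbln2 (2.47-fold). A second, far dimmer probe set of Tnc did not show the difference (0.09), and that of Msx2 read -0.27. The hyaluronan and proteoglycan genes Has2 and Vcan, which make up the cardiac jelly, moved apart: Has2 had log2 ratios of -0.30 and -1.13 on its probe sets, and Vcan read 0.31 on its brightest and 0.52 to 2.58 on 5 others. Under every scaling tried the list's median stayed below 0 and below the random lists. Scaling to the poly-A controls (median log2 ratio -1.05) was not tried. It would raise every ratio alike and take this median above 0, with the percentile unchanged. Epithelial (median 1.19, as bounds) and inflow genes (0.91) were higher in the same pool. How much neighbouring tissue each pool held was not measured.

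The TGF-beta and BMP pathway list had a median of 0.30 over 22 members (percentile 99.65), a value that turned to -0.29 under scaling to the hybridization controls while the percentile stayed the same. Smad7, an inhibitor of the pathway, was 2.28-fold higher on its brightest probe set but read 0.15 on the other, and the endothelial receptor gene Acvrl1 was at least 2.51-fold higher. Bmp2 read 0.98, Bmpr1a 0.84 (0.04 to 0.46 on its 4 other probe sets) and Bmp4 -0.35.

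WNT pathway genes went both ways. The list's median of -0.11 over 18 members lay within random lists (percentile 31.3). Rspo3, a WNT agonist, was 3.11-fold lower (1685 and 542), Wnt2 2.89-fold, the effector gene Lef1 2.51-fold, Wnt4 2.42-fold and the antagonist gene Dkk1 2.07-fold lower. The receptor genes Fzd1 and Fzd7 were 3.24-fold and 2.47-fold higher. Second probe sets of Rspo3 (-1.74), Lef1 (-0.70), Wnt4 (-0.80), Dkk1 (-0.91, a bound) and Fzd1 (0.94) had the same sign as the first. The RA-treated signal of that Dkk1 probe set was under the floor.

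Genes known to respond to RA were higher in the RA-treated pool. All 12 measured members of the RA-responsive list had a ratio above 0, with a median of 0.65 (percentile 99.99). Cyp26a1, which degrades RA, was 4.22-fold higher (128 and 539), the retinaldehyde reductase gene Dhrs3 4.05-fold (92 and 371) and the receptor gene Rarb 2.34-fold (576 and 1348). Cyp26b1 read 0.98 and Nrip1 0.99. Among enzymes, carriers and receptors of retinoids only the carrier gene Rbp4 passed 2-fold (2.23-fold higher), and the list's median of 0.36 over 11 members lay within random lists (percentile 92.7), though above them after loess (0.36, percentile 98.2) and quantile scaling (0.32, 98.1).

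Anterior Hox genes, which set position along the body axis and answer to RA, were higher where they could be measured. The 7 members above the floor had a median of 0.71 (percentile 99.85). Of these, 5 exceeded the floor on the RA-treated array only, so the median rests on bounds, and it was 0.40 after loess and after quantile scaling (percentiles 99.83 and 99.86). Among them were Hoxb4, at least 3.21-fold higher, Hoxb2, 2.43-fold, and Hoxb3, 2.37-fold. Signals were low: the highest, that of Hoxb2, was 221 in the control and 536 in the RA-treated pool, and genes in the lowest decile of signal had a median ratio of 0.23. Under the floor at the 60th percentile too few members were left for a comparison. Only 3 posterior Hox genes exceeded the floor, and their median was -0.03. Pharyngeal endoderm and epithelial genes were higher in the same pool (median 1.19, as bounds), and the share of neighbouring tissue was not measured.

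Regulators of the second heart field, the progenitor population that builds the outflow tract, stood above random lists, with a median of 0.39 over 19 members (percentile 99.11). Scaling to the hybridization controls, which shifts every gene alike, turned this median to -0.19 and left the percentile at 99.11; with the floor at the 60th percentile the median was 0.23 (percentile 95.2). Genes of the neighbouring pharyngeal endoderm and epithelium were higher by more (median 1.19, as bounds, and given below), and how much neighbouring tissue each pool held was not measured. Prdm1 was 5.95-fold higher, Six2 at least 2.66-fold, Mef2c 2.27-fold, Foxc2 2.10-fold and Isl1 2.06-fold (1697 and 3503). The other probe set of Isl1 read 0.99, whereas those of Mef2c ranged from -0.49 to 0.32. Wnt11 read -0.96 and the muscle methyltransferase gene Smyd1 -0.78, and the core cardiac factors Nkx2-5, Gata4 and Hand2 lay between 0.02 and 0.23 on their brightest probe sets, but the other probe set of Gata4 read -0.91 and those of Hand2 -0.62 and -0.41. Inflow and proepicardial genes had a median of 0.91 over 10 members (percentile 99.99). Upk3b was 2.73-fold higher, Wt1 2.55-fold, Shox2 at least 2.15-fold and Tbx18 2.11-fold. Nr2f1 and Nr2f2 both read 0.91.

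Of the lists of pharyngeal epithelium, neural crest, neurons, endothelium, blood cells and smooth muscle, only the first stood apart from random lists with the values as deposited. Pharyngeal endoderm and epithelial genes had a median of 1.19 over 13 members (above all 10000 random lists), and 2 members read below 0. At least 2-fold higher were 7 members: Krt8, Krt18, Krt19 and, as bounds, Cdh1, Cldn6, Epcam and Sox2. Of these 13, 5 exceeded the floor on the RA-treated array only, and the median is itself such a bound, that of Sox2 (4.2 and 107.1). Over the 8 members above the floor on both arrays the median was 0.60 (percentile 99.67), and only 3, the keratin genes, passed 2-fold. Over all 13 members the median was 0.88 after loess and after quantile scaling, above all random lists. The keratin genes, which are also expressed outside endoderm, were the brightest: Krt19 was 5.10-fold higher (1266 and 6458), Krt18 3.37-fold and Krt8 3.23-fold. The adhesion genes Cdh1 and Epcam were at least 3.10-fold and 2.28-fold higher, from control signals under the floor. Epcam has no settled direction: its brighter probe set, which ends in _x_at and lies above both floors, read -0.76 (144.3 and 85.5). Neural crest genes had a median of 0.36 (percentile 91.3, but 98.4 with a pseudocount in place of the floor), with Sox10 2.76-fold and Plxna2 2.11-fold higher. Neural tube and neuron genes had a median of 0.22 (75.2), with Isl2 2.10-fold higher and Tubb3 at -0.90. Endothelial and endocardial genes had a median of 0.13 (91.7), with the VEGF receptor genes Flt1 3.18-fold and Kdr 2.20-fold higher and Tek at -0.38. The macrophage list had no settled direction: its median was 0.18 (42.5) as deposited, -0.11 after loess and -0.13 after quantile scaling, and 3 of its 8 members (Cd68, Ptprc and Tyrobp) had control signals between the floors of the arrays and lower signals in the RA-treated pool; without these it was 0.62 (percentile 93.3). Medians were 0.33 (percentile 94.0) for erythroid genes and 0.00075 (41.1) for smooth muscle genes, in which Myh11 was at least 2.10-fold higher and Lmod1 read -0.86. After loess and quantile scaling the medians shrank to 0.130 and 0.033 for erythroid, 0.061 and 0.058 for neural crest, 0.079 and 0.040 for endothelial and 0.022 and -0.0045 for neural genes, all within random lists.

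**Figure D2:**
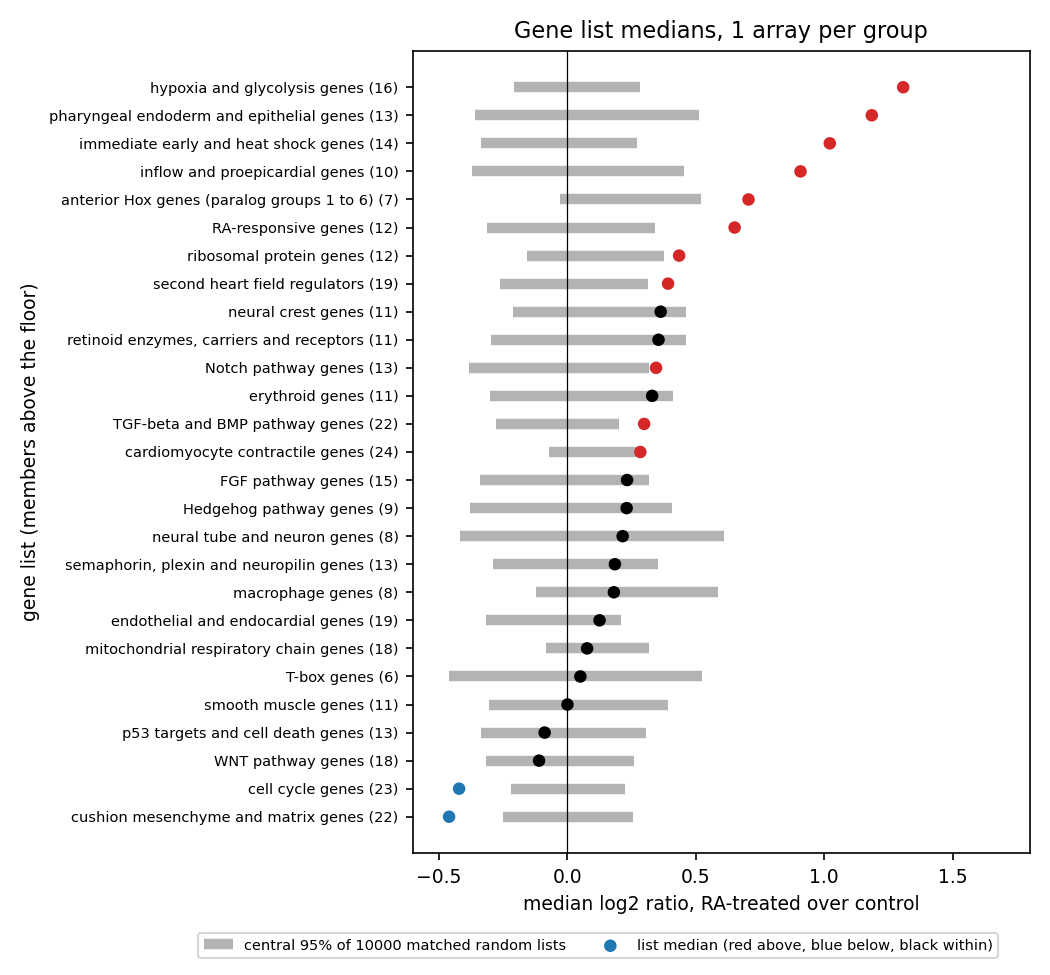
Median log2 ratio (RA-treated over control) of each of the 27 gene lists with a percentile (points; red above, blue below, black within) against the central 95% of 10000 random lists matched on signal (grey bars), with the number of members in brackets. 11 lists lie above and 2 below. The second heart field, TGF-beta and BMP, Notch, contractile and ribosomal protein medians turn below 0 under scaling to the hybridization controls, which shifts every gene by the same amount and leaves the percentiles as they are; the contractile and ribosomal protein medians turn below 0 under quantile scaling too, where neither list is apart.

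Genes of the response to low oxygen and of glycolysis showed the highest list median. All 16 measured members had a ratio above 0, with a median of 1.31, above all 10000 random lists, and 10 were at least 2-fold higher. They included the carbonic anhydrase gene Car9 (7.54-fold), the prolyl hydroxylase gene Egln3 (7.36-fold, 307 and 2260), Ankrd37 (6.93-fold), the peptide hormone gene Adm (6.89-fold), the mitophagy gene Bnip3 (3.63-fold) and Vegfa (2.84-fold). Of the 15 named genes with the highest ratios, Ndrg1 was first (25.96-fold, 84 and 2181), and Ddit4, an inhibitor of mTORC1 signalling, was 15.9-fold higher (378 and 5992). Rgcc was 17.4-fold, Ndufa4l2 11.8-fold, the glycolytic genes Eno2 11.2-fold and Aldoc 9.44-fold, the lipoprotein receptor gene Vldlr 10.2-fold, Igfbp3 8.05-fold and the metallothionein gene Mt1 8.26-fold higher. A second probe set was higher by less for Rgcc (4.38-fold) and Igfbp3 (3.29-fold). The value of Mt1 rests on 1 probe set ending in _s_at, and its other probe set was under both floors (15 and 14). The 4 other probe sets of Ndrg1 had log2 ratios from 3.13 to 5.22 (8.77-fold to 37.4-fold higher). Immediate early and heat shock genes, which respond within minutes to handling and stress, were higher too, with a median of 1.02 over 14 members (above all 10000 random lists). Ier3 was 12.7-fold, Hspa1a 4.63-fold and Fos 3.27-fold higher, while Ier2 was 2.26-fold lower. The 3' to 5' ratios of Tfrc and Pcx given above differed between the same pools, while those of Actb and Gapdh differed little. In the spiked-in poly-A controls, which do not come from the tissue, 5' probe sets were lowered more than 3' ones as well. Their log2 ratios at 5' and 3' were -1.85 and -0.87 for thr, and -1.68 and -1.04 for dap, on the r2 probe sets. The shift is therefore not particular to the tissue's RNA.

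Cell cycle genes were lower. Of 23 members 22 had a ratio below 0, the median was -0.42, below all 10000 random lists, and it stayed below them or at a percentile of at most 0.02 in every alternative. Only Rrm2, which supplies deoxyribonucleotides, passed 2-fold (2.48-fold lower, 7204 and 2904). Aurka read -0.75, Mcm2 -0.75 and the proliferation marker Mki67 -0.73. The list of p53 targets and cell death genes had a median of -0.09 and a mean of 0.05 (percentile 33.1), with the pro-apoptotic genes Bcl2l11 and Bbc3 2.38-fold and 2.06-fold higher and Aen 2.22-fold lower.

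**Figure D3:**
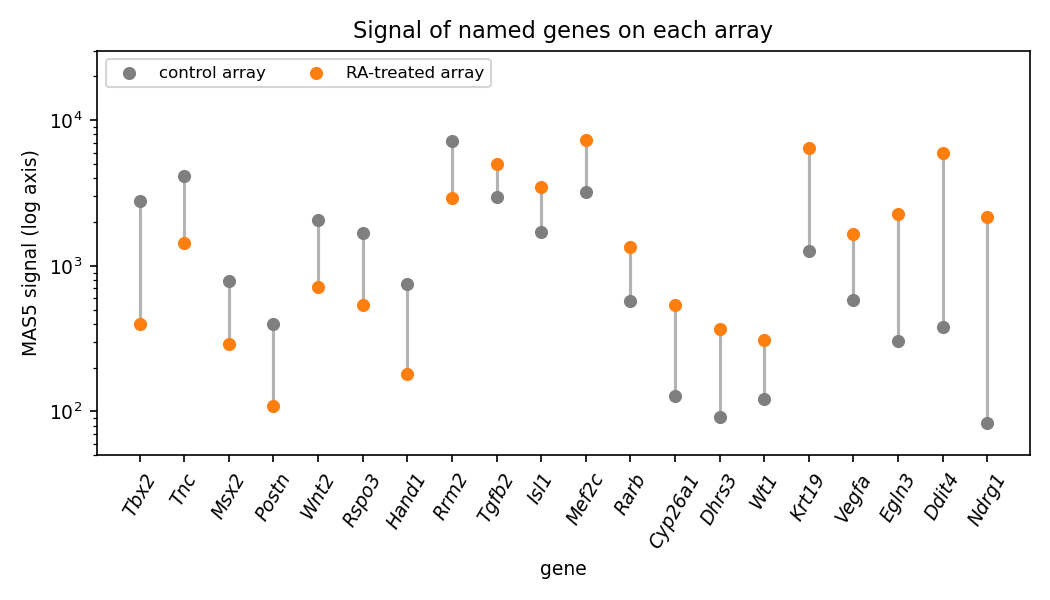
MAS5 signal (log axis) of 20 named genes on the control array (grey) and the RA-treated array (orange), 1 array each, with a line joining the pair. Tbx2 lies at 2773 and 396 (control and RA-treated) and Ndrg1 lies at 84 and 2181; no error bar can be drawn without replicates.

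Contractile genes of the myocardium had a median of 0.28 over 24 members (percentile 97.64), which was 0.05 after loess and -0.07 after quantile scaling, neither apart from random lists, and -0.30 under scaling to the hybridization controls. Nppb, a stress-responsive natriuretic peptide gene, was 2.40-fold higher (5233 and 12566), while Nppa read -0.26. Ribosomal protein genes behaved alike, with a median of 0.44 over 12 members (percentile 99.02) that was 0.11 after loess, -0.03 after quantile and -0.15 after hybridization-control scaling. Rps24 was 2.73-fold lower on its brightest eligible probe set, but its 5 other probe sets read 0.39 to 0.61. The 0.39 is a bound, since that probe set's control signal was under the floor. The mitochondrial respiratory chain list had a median of 0.08 and a mean of -0.01 (percentile 38.5), and its median was -0.24 after quantile scaling (percentile 0.28).

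Of the other signalling lists, the Notch pathway had a median of 0.35 over 13 members (percentile 98.1), with the target gene Hey1 2.86-fold higher and Nrarp at -0.71; the percentile was 97.3 with the floor at the 20th percentile, and the median was -0.24 under hybridization-control scaling, at the same percentile of 98.1. The FGF pathway median was 0.23 (percentile 92.7, but 97.58 after quantile scaling and 97.7 with the floor at the 20th percentile), with the feedback inhibitor genes Spry2 2.11-fold and Spry1 2.002-fold higher and Fgfr3 2.46-fold lower on its brightest probe set (-0.13 on the other); the ligand genes Fgf8 and Fgf10 read 0.98 and 0.92 from low signals. The Hedgehog list and the semaphorin, plexin and neuropilin list had no settled direction. The first had a median of 0.23 (85.5), with Ptch1 at 0.70, which was 0.10 without Gli1, a gene near the floors, -0.021 with a pseudocount, -0.041 without probe sets ending in _x_at or _s_at, -0.011 with the floor at the 60th percentile and -0.0004 after quantile scaling. The second had one of 0.19 (82.1), with Nrp2 at -0.72, which was -0.21 with that floor, -0.006 after loess and -0.029 after quantile scaling. Of left-right genes only Cfc1 and Tdgf1, which encode Nodal co-receptors, were above the floor, and both were lower, by 2.12-fold and 2.06-fold. Of the sex chromosome genes, Xist was 3.63-fold higher (1312 and 4762), while the Y-linked genes Eif2s3y, Uty and Kdm5d read 0.28, 0.24 and -0.25 on their brightest probe sets. The 3 other probe sets of Uty ranged from -0.72 to 1.35, so the direction of Uty is not settled. The 1.35 is a bound, since that probe set's control signal was under the floor.

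The remaining genes with the lowest ratios were Stard8 (4.17-fold lower), Plac1 (3.31-fold), Pkia (3.09-fold), the cartilage collagen gene Col9a1 (3.04-fold) and Gpd1l (2.80-fold). Itpa, Zw10, Tlcd4, Fam13b and Ly6e were 2.84-fold to 3.30-fold lower on their brightest probe sets, but other probe sets of these genes had ratios above 0. Among the highest were also the nuclear RNA Malat1 (23.8-fold) and the protease gene Cpa1 (7.50-fold). The 6 other probe sets of Malat1 had log2 ratios from 0.15 to 2.84 (1.11-fold to 7.15-fold higher). Of the genes above the floor on the RA-treated array alone, Nrn1 was at least 14.0-fold and the galectin gene Lgals3 at least 10.8-fold higher, followed by Pou5f2, Kcne3 and Gad1. Of those above it on the control array alone, Cthrc1 was at least 6.53-fold and the chemokine gene Ccl2 at least 5.74-fold lower, followed by Crispld1, Grhl1 and Hlcs.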

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

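The level-matched test, the test of Y-linked genes and the narrower list of nuclear RNAs were chosen after the results were seen; the tests of other nuclear RNAs and of dim probe sets were set before theirs.

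A signal outside the comparisons lies in the probe sets that have no gene name here. Of 2840 such probe sets above the floor on both arrays, 859 (30.2%) were at least 2-fold higher in the RA-treated pool and 39 (1.37%) at least 2-fold lower, against 5.14% and 2.47% of named genes. The 5' control probe set for 18S ribosomal RNA read 9372 and 38370, 4.09-fold higher, whereas the 3' and middle probe sets of the same RNA were 2.41-fold and 1.94-fold lower.

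The excess among unnamed probe sets occurred in the same pool as the higher Malat1 and Xist, and 2 arrays cannot show whether they are linked. Low signal of the unnamed probe sets is argued against as the cause of their excess, since only 9.68% of named probe sets matched on signal were 2-fold higher (SD over draws 0.56). A larger share of female embryos is argued against for Xist if the control pool was near equally male and female, because a log2 fall of at least 1 in Y-linked genes would then be needed: Eif2s3y read 0.28 and Kdm5d -0.25, and Uty, with no settled direction, gave the median of 0.24 and -0.72 on its lowest probe set. A list of other long non-coding RNAs taken as nuclear had a median of 0.47 over 15 members (percentile 99.5, but 95.2 with the floor at the 20th percentile and 97.3 with the mean of all probe sets). The list held RNAs that are not mainly nuclear. Without its measured members Norad, Gas5, Snhg1 and Snhg3 the median was 0.73 over 11 members (percentile 99.8), the bound of Pvt1 (44.4 and 78.1). It was 0.78 over the 9 members above the floor on both arrays (99.9), but 0.43 after loess (98.7), 0.42 after quantile scaling (99.0) and 0.41 with the mean of all probe sets (96.3). This is consistent with a higher share of nuclear transcripts, but no value here measures where an RNA lies in the cell. Whether probe sets outside mature transcripts picked up unspliced or genomic template stays open: dim probe sets of named genes had a median ratio -0.013 from that of matched bright ones, but this median mixes exonic with other probe sets and cannot show a minority, and 14.2% of them were 2-fold higher against 7.58% of the matched; an effect of RA itself is untested.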

How the results depend on the processing

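No paired analysis was possible because each group is 1 array. The counts depended on threshold and floor: 1186 genes higher and 503 lower with the floor at the 20th percentile, 334 and 177 at the 60th, 1647 and 1323 at 1.5-fold, 157 and 26 at 3-fold, and 142 lower with a pseudocount. Scaling to the hybridization controls, chosen after seeing the data, gave 157 and 2279; it moves every gene by one factor, so the ratios kept their order and the lists their percentiles, and it took the medians of the second heart field (-0.19), TGF-beta and BMP (-0.29), Notch (-0.24), contractile (-0.30) and ribosomal protein lists (-0.15) below 0. Scaling to the poly-A controls (median log2 ratio -1.05) was not tried. It would raise every ratio alike, also without changing percentiles, and take the cushion and cell cycle medians above 0. The contractile median was 0.055 after loess, -0.065 after quantile scaling and 0.28 with the floor at the 60th percentile, where it was within random lists. Ribosomal protein genes gave 0.11 after loess and -0.032 after quantile scaling, and the mitochondrial list -0.24 after quantile scaling; the cause was not tested. At the 60th percentile floor the second heart field list (0.23) was within random lists, and the anterior Hox (0.76) and epithelial (1.72) lists kept too few members. The Notch list (0.35) left the call with the floor at the 20th percentile and without _x_at and _s_at probe sets. Calls were gained as well: retinoid enzymes after loess (0.357) and quantile scaling (0.318), FGF after quantile scaling (0.275) and with the floor at the 20th percentile (0.349), and neural crest with a pseudocount (0.556). Leaving out genes between the floors, chosen after seeing the data, changed no list's call. With only members above the floor on both arrays, chosen after seeing the data, the contractile list (0.284) was within random lists (percentile 97.17), the anterior Hox list (1.26) kept too few members, and the epithelial median was 0.60 and apart. The anterior Hox median fell to 0.40 after loess and quantile scaling and stayed apart. Fam13b (1.28) and Ly6e (0.28) without _x_at and _s_at probe sets, and Rps24 (0.20) and Tlcd4 (0.045) as means of all probe sets, turned sign; these ratios rest on single probe sets. Of 106 named genes at 2-fold or more, 47 had another probe set above a floor; in 38 all others had the same sign, in 18 all were 2-fold too, and in 9 at least 1 had the opposite sign. 66 of the 106 stayed 2-fold in the same direction under every setting fixed in advance in which they kept a probe set, among them Tbx2, Hand1, Rspo3, Wnt2, Postn, Rarb, Cyp26a1, Isl1, Krt19, Egln3 and Ndrg1. A gene left with only a probe set under both floors counted as not kept. Mt1 was such a gene without probe sets ending in _x_at or _s_at (15 and 14). The medians of the RA-responsive, inflow, immediate early, hypoxia, TGF-beta and BMP, cushion and cell cycle lists kept their direction and stood apart from random lists under all settings fixed in advance. That of the TGF-beta and BMP list turned below 0 under the added scaling to the hybridization controls. Signals near the floor limit Hox, Epcam, Cdh1 and Sox2.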

Other observations

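The tests of loess scaling, handling and muscle share were chosen after the results were seen; those of second probe sets, of the brightest genes and of ribosome production were set before theirs.

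Factors that make ribosomes were lower in the RA-treated pool. Bop1 (2.72-fold lower), Ftsj3 (2.70-fold) and Trub2 (2.62-fold) were noticed among low ratios, and a list of 39 other such factors was then written and measured. Its median was -0.55, below all 10000 random lists under each setting tried; 36 of the 39 members had a ratio below 0 and 7 were at least 2-fold lower. Rrp12 was 2.49-fold, Nolc1 2.45-fold, Rrs1 2.33-fold and the RNA polymerase I subunit gene Polr1a 2.13-fold lower, whereas the abundant nucleolar gene Npm1 read 0.48.

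Among imprinted non-coding RNAs, Kcnq1ot1 was 2.11-fold higher, with log2 ratios from 0.77 to 1.03 on 3 other probe sets. Airn had a log2 ratio of 0.78, with 4 other probe sets from 0.59 to 1.33. Meg3 was 4.10-fold higher on its brightest probe set, but 10 others had log2 ratios from -0.76 to 1.01. Mirg (1.25, other probe set -0.47) and Rian (-0.93, others from -0.62 to 1.87) had no settled direction.

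The higher hypoxia and glycolysis genes may have come from the treatment or from the tissue's handling. Intensity-dependent scaling is argued against, since the median after loess was 1.38, above all 10000 random lists. Probe sets that pick up other transcripts are argued against as well, since second-brightest probe sets of 11 members had a median of 0.99. A longer time without oxygen between dissection and stabilization would also raise immediate early and heat shock genes, whose median was 1.02, but RA could move the same genes, and with 1 pool per group the 2 explanations cannot be told apart.

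The contractile and ribosomal protein lists had medians above 0, although 4 of 24 and 3 of 12 members read below 0. Whether a higher share of muscle adds to this stays open: of the contractile genes 16 lie among the 200 brightest, where saturation may hide a rise, and the 8 others had a median of 0.062, below the list's 0.28 but with an SD of 0.54 (from -0.36 to 1.26). An array scale factor carried by near-saturated probe sets is a candidate explanation, and loess or quantile scaling ended the call of both lists. The 200 brightest genes had a median of 0.34 with an interquartile range of 0.34. This median differed from that of the hybridization controls by -0.24, within the 0.3 set in advance. That limit is nearly as wide as the 0.34 itself, and 16 of the 200 genes are contractile list members, so the comparison is weak.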
